A study of Zalophus californianus with 73 samples.

How the data were processed

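Total RNA from whole blood of California sea lions was labelled with Cy3 from an input of 500 ng and hybridised to an Agilent 1-colour canine array, per the labels' protocols. Scans were read with Agilent Feature Extraction, per the submitters' processing notes; its version is not given in the sources used here. The 73 deposited columns of intensity values, made by the authors, are on a linear scale, were not brought to a common level between arrays, and list 15743 numbered probes without gene names, the lowest value being 0.831. Of these columns, 0 were left unused. The 4 deposited tables of group averages, made by the authors with Resolver per the file names, give for each gene an average intensity in linear units, an error and a p-value. How the authors weighted and normalised these average intensity values and treated repeat arrays is not given in the sources used here. The deposited error is in intensity units, and whether it is a standard error is not stated by the authors. The deposited p-value of each average lay under 0.01 in every case, so that dim genes are absent. Neither the platform's annotation nor the scanner files were used here.

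The averages listed 15188 genes or transcripts, 13432 of them in all 4 groups, and 6927 had a readable gene name. None of the accessions (0) or LOC numbers (0 of 7149) occurred in the sea lion gene table at hand, so names are those of the deposited tables, which describe dog genes. The numbered probes share no identifier with the averages, and no attempt was made to pair them by value or order. The planned rule for named genes and the planned camera tests of gene lists needed named probes and could not be applied as written. The rule was adapted before the averages were compared, and some of the genes it took are not reported here. Named are the 8 readable genes with the largest clear gap on each side for DAT over Healthy, Lepto over Healthy and DAT over Lepto, and the 5 largest on each side for the other comparisons (all where fewer exist), with 2 members of each list that stood apart. ALAS2, alpha-spectrin and TNFRSF1B, and genes of the closing observations, were chosen after their values were seen, and a gene named for 1 comparison may keep its values in others. A clear gap needed a ratio of at least 1.5 after centring on the median ratio of the 13432 shared averages, which was 0.14 for DAT over Healthy, 0.12 for Lepto over Healthy, 0.06 for DAT over Lepto, 0.04 for Outgroup over Healthy, 0.09 for DAT over Outgroup and 0.04 for Lepto over Outgroup on the log2 scale, and a difference of over 3 combined deposited errors. The median deposited error was 8.18% of the average in DAT, 12.6% in Lepto, 14.0% in Outgroup and 7.28% in Healthy, so that fewer gaps can be clear in Lepto and Outgroup.

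Gene lists for cell types and pathways, 24 in number, were written before the data were examined, and their members were matched to the averages by name and description only. One average per symbol, the brightest, entered a list, and list medians were set against 10000 random lists of the same size matched on mean intensity in 20 bins. A list stood apart below the 2.5 or above the 97.5 percentile, which describes these averages and is no test over animals. The basophil and mast cell list had 2 measured genes and was not summarised. In simulated use, 5.5% of 200 random lists of 15 genes among 6193 stood apart for DAT over Healthy, and a list shifted by 0.75 on the log2 scale lay at percentile 100.0. Both kinds of random list came from the same genes, so a share near that value was set in advance. Whether genes of a real list move together was not covered. Of 23 lists, 5 stood apart for DAT over Healthy, 8 for Lepto over Healthy and 10 for DAT over Lepto. For Outgroup over Healthy, DAT over Outgroup and Lepto over Outgroup, 8, 4 and 12 did.

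Probe intensities were converted to log2 and quantile-normalised, because array medians spanned 4.72 on the log2 scale. Repeat arrays of 5 animals were averaged, leaving 1 value for each of 67 animals. A model with diagnosis alone was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and probes were called at a Benjamini-Hochberg adjusted p under 0.05. Acute and chronic DAT animals, females and males (with diagnosis and age class as covariates) and a nearest-centroid classifier of DAT and Lepto on 50 probes were handled as planned before the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the classifier, the averages and the figures. Slides were taken as batches, and slides with a median array intensity above 500 were called bright. Fits that used slide took the first array of each animal. The consensus correlation of arrays was 0.537 within slides and 0.323 within animals where these were random blocks.

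The limma step was tested on simulated data with the real spread of 15743 probes and 200 changed probes. Of those changed by 1 on the log2 scale it recovered 9.00% for DAT minus Healthy, 8.00% for Lepto minus Healthy, 61.0% for DAT minus Lepto, 1.00% for Outgroup minus Healthy, 47.0% for DAT minus Outgroup, 43.5% for Lepto minus Outgroup and 59.0% for females minus males. Of those changed by 2 it recovered 68.5%, 67.0%, 94.0%, 63.0%, 94.5%, 90.0% and 95.0% in the same order. Alternatives covered slide as a fixed or random block, sex and age class, other normalisations, a pseudocount of 50, a filter on dim probes, array weights, repeat arrays, each Healthy animal left out and a stricter adjusted p of 0.01. Runs on bright or dim slides alone, with the slide set as a block, with the side of the slide as a term and without 2 animals with very bright arrays were added after seeing the data.

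For the classifier, simulated DAT and Lepto animals with 2000 probes gave a balanced accuracy of 26.4% with no difference and 100.0% with 100 probes shifted by 2 SD. The scale of the values as linear intensity was read from their range, and whether the authors normalised them is unknown. The median intensity of each array follows by slide. Medians on slide 1 were 1154, 1114 (Lepto), 991 (Outgroup). Medians on slide 2 were 1352, 818, 1068, 1033, 1218 (Lepto), 1068, 932 (Outgroup). Medians on slide 3 were 778, 675 (DAT), 1005, 944, 639 (Lepto), 955, 968 (Outgroup). Medians on slide 4 were 1054, 899 (DAT), 288, 855 (Lepto), 952, 3249 (Outgroup). Medians on slide 5 were 255, 190.0, 251 (DAT), 148, 173, 196, 124 (Healthy), 173 (Lepto). Medians on slide 6 were 243, 176 (DAT), 209, 184 (Outgroup). Medians on slide 7 were 1127, 1072, 3277, 1145 (DAT), 944, 1147 (Lepto), 1137 (Outgroup). Medians on slide 8 were 226, 229, 214, 199, 185, 186, 247 (DAT). Medians on slide 9 were 177, 125 (DAT), 138, 138 (Lepto), 185 (Outgroup). Medians on slide 10 were 159.7, 188 (DAT), 186 (Lepto). Medians on slide 11 were 265, 313, 268, 205, 243, 216, 197 (DAT), 204 (Lepto). Medians on slide 12 were 209, 203 (DAT), 166, 158, 172, 150.2, 155 (Lepto), 203 (Outgroup).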

Results

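Blood was taken into RNA-stabilising tubes from California sea lions (Zalophus californianus) at a rehabilitation centre, and its total RNA was labelled with Cy3 and hybridised to a 1-colour array built for the dog. The 73 arrays came from 67 animals in 4 groups set by preliminary diagnosis. DAT, poisoning by the algal toxin domoic acid, held 30 animals on 33 arrays. Lepto, infection with the bacterium Leptospira, held 21 animals on 24 arrays. Outgroup, animals with other diseases, held 12 animals and Healthy held 4 control animals, each on 1 array. DAT had 16 females, 13 males and 1 animal of unstated sex, Lepto had 2 females and 19 males, Outgroup had 7 females and 5 males, and all 4 Healthy animals were adult males. Each array gave 15743 probe intensities without gene names, and the authors' averages per group gave gene names without replicates. Tests over animals are therefore given as counts of unnamed probes, and named genes are described by the deposited averages alone. The number of arrays limits the precision.

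Named genes carry the deposited average intensity of a group and, after ±, the error deposited with it, which has no stated number of replicates. Ratios of averages are on the log2 scale, after taking away the median ratio of the 13432 averages listed for all 4 groups, and a clear gap is a ratio of at least 1.5-fold that exceeds 3 combined deposited errors. No test over animals stands behind a clear gap, and averages of different groups come from separate files whose normalisation the sources used here do not give. Of the arrays, 24.2% in DAT, 58.3% in Lepto, 66.7% in Outgroup and 0% in Healthy lay on the 5 slides called bright here. Averages lay in the order of these shares for 21.4% of all genes and, among clear gaps, for 13.6% in DAT over Healthy, 32.3% in Lepto over Healthy, 18.3% in DAT over Lepto, 42.2% in Outgroup over Healthy, 19.7% in DAT over Outgroup and 12.5% in Lepto over Outgroup.

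**Figure D1:**
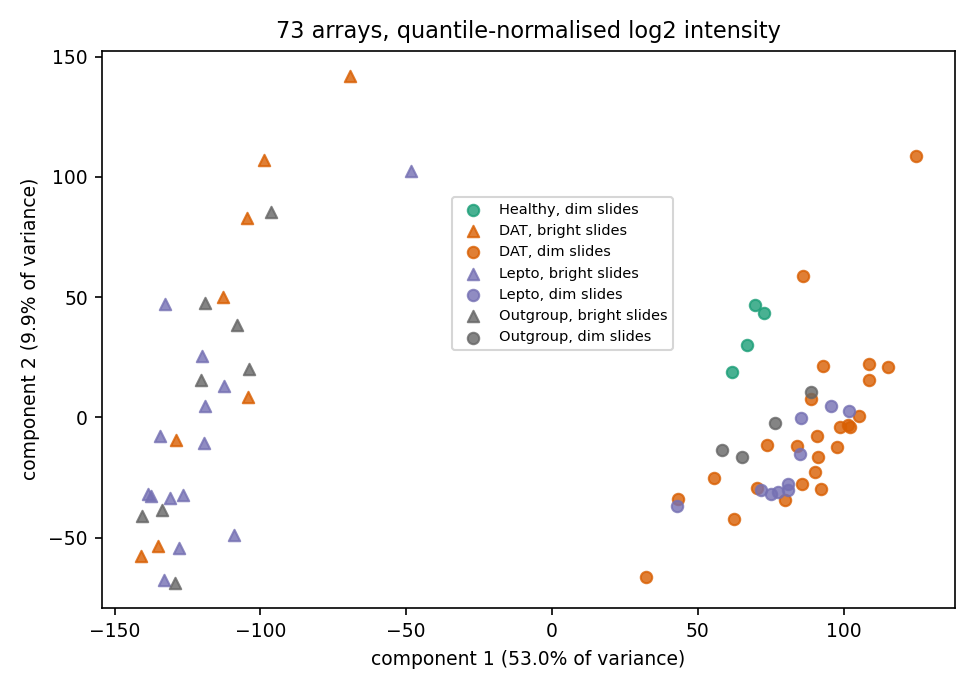
Quantile-normalised arrays on the first pair of principal components, coloured by diagnosis, with triangles for the 5 bright slides and circles for the 7 dim slides. Component 1 held 53.0% of the variance and parted the bright from the dim slides.

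Slide and diagnosis overlapped only in part. Array medians ranged from 124 to 3277 intensity units, with a median of 1019 over the 30 arrays on slides 1, 2, 3, 4 and 7 and a median of 190.0 over the 43 arrays on the other 7 slides. After quantile normalisation, slide accounted for 0.979 of the variance of component 1 (R squared) and diagnosis for 0.188. Arrays of the same diagnosis correlated across probes with a median r of 0.970 on the same slide and 0.781 between a bright and a dim slide. All 4 Healthy arrays lay on slide 5, beside 3 DAT arrays and 1 Lepto array. Counts of probes between diagnoses and between sexes are given below also from a fit with slide as a fixed block.

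DAT against Healthy asks how the blood of poisoned animals differed from that of controls. The red cell list had a median towards lower averages in DAT. KEL (LOC482743), the Kell blood group protein of red cells, stood at 1039 ± 135 in Healthy and 151 ± 48.4 in DAT. The flavin reductase gene BLVRB (LOC476456), an abundant red cell enzyme, stood at 24355 ± 2463 and 3616 ± 708, and BPGM (LOC482704), which makes the red cell's 2,3-bisphosphoglycerate, at 7171 and 1137. Of the 18 erythroid genes measured, 8 had a clear gap towards lower averages in DAT and 1, alpha-spectrin (LOC488616), towards higher. The list's median log2 ratio of -0.46 lay at the 0.0200 percentile of random lists matched in size and mean intensity. ALAS2, the erythroid enzyme that starts haem synthesis, had no clear gap, with a log2 ratio of 0.29.

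The largest gaps towards lower averages in DAT included genes with very bright signals in Healthy. Averages labelled semaphorin B (LOC490416), the transcription factor sal-like 2 (LOC482568) and NHLRC1, a ubiquitin ligase, stood at 124502, 107538 and 72663 in Healthy and at 13286, 12270.2 and 7896 in DAT. Bagpipe homeobox 1 (LOC488822), a developmental transcription factor, had a log2 ratio of -3.46. The kainate receptor subunit glutamate receptor 6 (LOC482474), a receptor type that domoic acid activates in brain, stood at 24352 ± 2935 in Healthy and 2679.8 ± 855 in DAT. Its average was also below Healthy in Lepto, at 1728 ± 589, and in Outgroup, at 5965 ± 2360, so a low value was not particular to DAT. The median of all 10 glutamate receptor and transporter genes was -0.13, or 0.02 without centring. Complement component C2 (LOC474853), a protease of the classical pathway, had a log2 ratio of -3.52, and LOC481213, described as a leucine zipper protein, one of -3.14.

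The largest gaps towards higher averages in DAT were 2 genes described as translation elongation factor EEF1A1 (LOC484225 and LOC481052), with log2 ratios of 2.17 and 1.81. The lysosomal membrane protein LAMP1 (LOC476995) stood at 233 ± 15.3 in Healthy and 864 ± 117 in DAT. ACADVL (LOC489463), which starts the breakdown of very long fatty acids in mitochondria, stood at 1413 ± 50.9 and 5064 ± 522. Cathepsin E (LOC488577), an aspartic protease, and versican (LOC488922), a matrix proteoglycan made by monocytes, each had a log2 ratio of 1.51, and the ceramide synthase homologue LAG1 homolog 2 (LOC483187) one of 1.74. Of 50 ribosomal protein genes, 9 were clearly higher and 1 clearly lower, with a list median of 0.31, and RPL9 (LOC475062) and RPL7A had ratios of 1.53 and 1.14.

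Further lists stood apart from random lists towards higher averages in DAT. In the complement list, properdin (LOC491859) and C3 (LOC484960) were among 3 clearly higher genes of 14, with log2 ratios of 1.28 and 1.14, and 2 genes were clearly lower, for a median of 0.42. In the glycolysis and hypoxia list, 3 of 19 genes were clearly higher and 2 clearly lower, with a median of 0.38. Platelet phosphofructokinase (LOC478019) and lactate dehydrogenase A (LOC490690) had ratios of 0.93 and 0.70. The glucocorticoid response list had a median of 0.37, or 0.23 with the mean of all averages of a symbol, which was not set against random lists, with DUSP1 (LOC489117), a phosphatase that damps MAP kinases, as its 1 clear gap of 13 genes, at 0.66. Medians were 0.29 for 13 mature neutrophil genes, 0.11 for 19 inflammatory cytokine genes and -0.02 for 14 T cell genes, within the range of random lists. Without centring they were 0.43, 0.26 and 0.12. In all, 950 averages were clearly higher and 1256 clearly lower in DAT. Without centring the ratios, 1647 were higher and 815 lower.

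Over animals, limma called 1245 of 15743 probes at an adjusted p under 0.05, of which 579 rose and 666 fell in DAT. Among called probes the median size of the difference was 1.70 on the log2 scale. In the fit with slide as a fixed block, 414 rose and 939 fell, and 666 of the 1245 were called again. The balance turned with the slide set as a fixed block, where 1617 rose and 1166 fell, and on the dim slides alone, where 2195 rose and 1524 fell. It also turned with array weights (4120 rose, 2829 fell) and among adult males (4413 rose, 3458 fell). The 5 adult male DAT animals lay on slide 11 and the 4 Healthy animals on slide 5, so that run cannot tell diagnosis from slide. Falls stayed more frequent with slide as a random block (325 rose, 819 fell) and with sex and age class as covariates (536 rose, 670 fell). Within slide 5, where 3 DAT arrays and 4 Healthy arrays lay together, 1061 rose and 1860 fell. The largest falls among unnamed probes called here and kept at an unadjusted p under 0.05 with slide as a block were probe 13034, at 16.98 ± 0.31 (SD, n = 4) in Healthy and 8.68 ± 2.47 (SD, n = 30) in DAT, and probe 5606, at 14.99 ± 0.28 (SD, n = 4) and 7.17 ± 2.54 (SD, n = 30), both on the log2 scale. Without Healthy replicate 3 or Healthy replicate 4, 811 and 710 probes were called. In the values as deposited, without normalisation between arrays, 87.9% of the calls were higher in DAT against 46.5% after it.

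**Figure D2:**
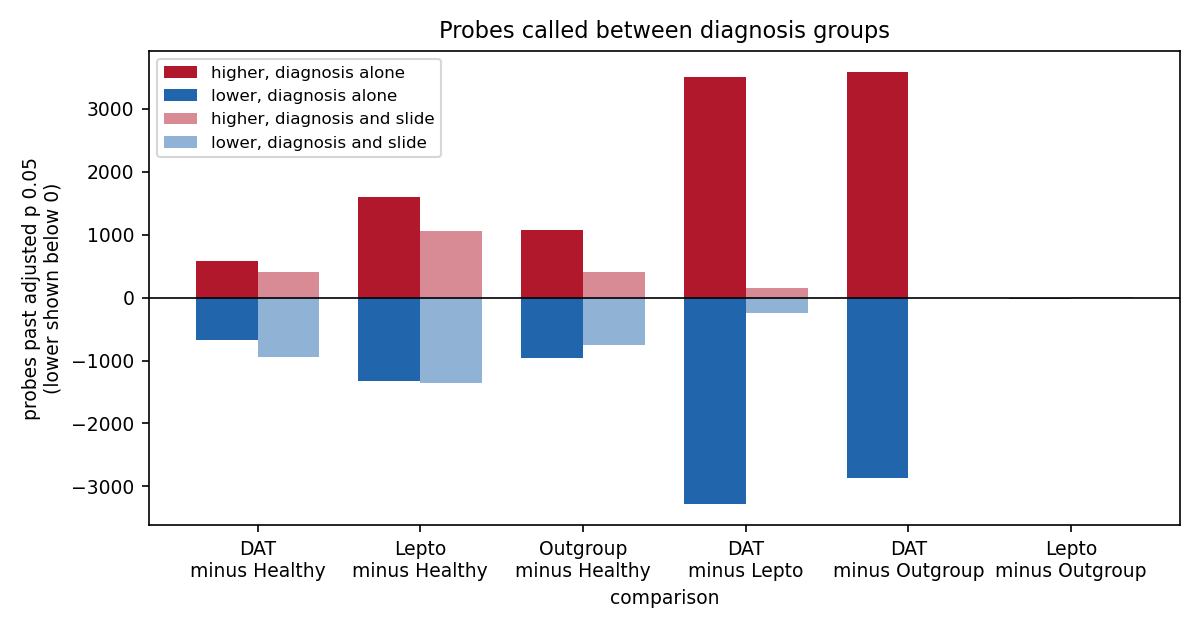
Number of probes past an adjusted p of 0.05 in limma, higher above 0 and lower below 0, with diagnosis alone (dark) and with slide as a further term (light). The 6776 calls between DAT and Lepto became 398 with slide in the fit, and the 1245 calls between DAT and Healthy became 1353, with 666 probes in both sets.

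Lepto against Healthy asks the same of animals with leptospirosis. The monocyte list had a median towards higher averages in Lepto, and the red cell and cytotoxic lymphocyte lists had medians towards lower averages. Of 10 monocyte genes, 6 were clearly higher and 1 clearly lower, with a median log2 ratio of 1.07, or 0.63 with the mean of all averages of a symbol. Versican stood at 486 ± 59.5 in Healthy and 4301 ± 1001 in Lepto, and the fibrinogen-like protein FGL2 (LOC475902), a product of activated macrophages, at 562 ± 45.4 and 3345 ± 813. CSF1R (LOC489188), the growth factor receptor of monocytes, had a ratio of 1.89, and TNFRSF1B (LOC491455) was the clearly lower gene, at -1.74. The complement list had a median of 0.59, with C1QB (LOC487381) and properdin (LOC491859) at 1.80 and 1.70, while C2 (LOC474853) was lower, at -4.21.

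Of 11 natural killer and cytotoxic genes, 5 were clearly lower and 0 clearly higher in Lepto, with a median of -0.95, below every matched random list. Cathepsin W (LOC483725), a protease of cytotoxic cells, stood at 3728 ± 475 in Healthy and 1209 ± 159 in Lepto, and granzyme A (LOC487207), a killing protease of their granules, at 10132 ± 1017 and 4072 ± 502. Of 18 erythroid genes, 9 were clearly lower and 0 clearly higher, with a median of -0.73. KEL stood at 65.3 ± 7.54 and BPGM at 476 ± 112 in Lepto. The platelet list had a median of -0.69, with 2 clearly lower and 2 clearly higher genes of 12. GATA1 (LOC480906), a transcription factor of red cell and platelet precursors that both lists hold, and SPARC (TC31800), a matrix protein stored in platelets, were lower at -2.04 and -1.73. Of 19 interferon-stimulated genes, 5 were clearly lower and 0 clearly higher, with a median of -0.38. IFIT2 (LOC479183) and IRF7 (LOC483406), which amplifies interferon production, had ratios of -1.98 and -1.42.

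Lists of protein synthesis and breakdown had medians towards Lepto. Of 50 ribosomal protein genes, 13 were clearly higher and 2 clearly lower, with a median of 0.49, led by RPL6 (LOC480924) and RPL23 at 2.31 and 1.93. Of 30 proteasome genes, 11 were clearly higher and 1 clearly lower, with a median of 0.43, and the subunits PSMB1 and PSMC2 (LOC475896) had ratios of 1.81 and 1.70. Medians of 0.58 for mature neutrophil genes, 0.42 for inflammatory cytokine genes, 0.19 for 8 genes of Toll-like receptor pathways, 0.26 for 6 neutrophil granule genes, 0.22 for 9 B cell genes and -0.03 for 7 plasma cell genes (0.09 without centring) lay within the range of random lists.

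The largest clear gaps among readable genes were wider in Lepto than in DAT. Idax (LOC487887), a regulator of Wnt signalling, stood at 416 in Healthy and 151053 in Lepto, and LOC485023, a gene named for leukaemia translocations, at 705 and 145977. The ubiquitin ligase CBL (LOC489369), beta-2-microglobulin (LOC478284), part of MHC class I, and EEF1A1 (LOC480975) had log2 ratios of 6.93, 4.66 and 4.15. In DAT, Idax, LOC485023 and CBL stood at 41438 ± 16671, 44125 ± 18143 and 2649 ± 1049, also above Healthy but without a clear gap. Brain protein 44 (LOC480086), SIPA1L1 (LOC480379) and band 4.1-like 2 (LOC484127) followed at 4.02, 4.05 and 3.95. On the lower side stood semaphorin B (LOC490416), NHLRC1, bagpipe homeobox 1 (LOC488822), sal-like 2 (LOC482568) and LOC481213, with ratios from -5.49 to -4.42, and the DNA helicase RECQL4 (LOC482101) at -4.30. Of the 32 genes that the rule for named genes took for Lepto, 9 had averages in the order of the groups' shares of bright slides, Idax among them, against 2 of the 24 taken for DAT. In all, 1875 averages were clearly higher and 2218 clearly lower in Lepto, or 2422 and 1704 without centring.

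Over animals, limma called 2915 probes between Lepto and Healthy, of which 1593 rose and 1322 fell in Lepto. Adding slide as a fixed block, 1056 rose and 1355 fell, and 1407 probes were called in both fits. Only 1 Lepto array shared a slide with Healthy, too few for a value within that slide. Without Healthy replicate 3 or Healthy replicate 4, 1765 and 1642 probes were called, and values as deposited put 95.5% of the calls on the higher side in Lepto against 54.6% after normalisation.

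DAT and Lepto were compared with the same 4 controls, so their differences share the chance values of these animals. Of the called probes, 461 rose and 645 fell in both, where independent lists of these sizes would share 58.6 and 55.9, and 0 moved in opposite directions. The log2 differences of both comparisons correlated across probes with r = 0.816, and unchanged groups simulated against the same 4 controls gave a mean r of 0.860. The covariance was 0.862 against 0.255 in the simulations. With the controls split 2 and 2 between the comparisons, r lay between 0.676 and 0.752 and covariance between 0.756 and 0.826. Both parts of the controls were adult males on the same side of slide 5. An effect of slide, side, sex, age or handling therefore stays common to both comparisons, and the simulations held no slide effect. In the fit with slide as a fixed block, 363 rose and 905 fell in both. Probes are not independent replicates.

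DAT against Lepto asks which signals set the toxin and the infection apart. The eosinophil, platelet and cytotoxic lymphocyte lists had medians towards DAT, and the monocyte, mature neutrophil and proteasome lists had medians towards Lepto. Among the 9 eosinophil genes, 3 were clearly higher in DAT and 0 lower, with a median log2 ratio of 0.68. The interleukin-5 receptor alpha chain (LOC476553), which eosinophils need for growth, stood at 575 ± 70.2 in DAT and 156 ± 20.6 in Lepto. C/EBP epsilon (LOC490607), a transcription factor of late granulocyte development, stood at 1449 ± 157 and 469 ± 63.6. In Healthy these genes stood at 718 and 811. Of 12 platelet genes, 3 were clearly higher in DAT and 0 lower, with a median of 0.61. P-selectin (SELP), the adhesion protein of platelet granules, stood at 968 ± 124 in DAT and 282 ± 52.7 in Lepto, and SPARC had a ratio of 1.27. Of 11 natural killer and cytotoxic genes, 3 were clearly higher in DAT and 0 lower, with a median of 0.65. Cathepsin W (LOC483725) had a ratio of 0.95, and NCR3, whose deposited description names lymphotoxin-beta instead, one of 0.78.

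On the Lepto side, 2 of 10 monocyte genes, FGL2 (LOC475902) and CSF1R (LOC489188), were clearly lower in DAT, at -2.45 and -1.30, and the list's median was -0.60. The mature neutrophil list had a median of -0.57 with calgranulin A (LOC490461), an abundant neutrophil alarm protein, as its 1 clear gap, at 128147 ± 12017 in DAT and 232315 ± 19908 in Lepto, while 6 neutrophil granule genes had one of -0.36, within the range of random lists. Of 30 proteasome genes, 11 were clearly lower in DAT and 0 higher, with a median of -0.45, PSMB1 and PSMA6 (LOC480290) at -1.31 and -1.24. Of 47 oxidative phosphorylation genes, 8 were lower and 1 higher, with a median of -0.35, NDUFB4 (LOC478577) and ATP5B at -1.07 and -1.01. Among 16 heat shock and unfolded protein response genes, the chaperones mortalin (LOC474697) and GRP78 (LOC480726) were clearly lower, at -1.59 and -1.29, with a list median of -0.54. The glucocorticoid response list had a median of -0.69 with 0 clear gaps among 13 genes, and ribosomal proteins one of -0.26 with 1 of 50 clearly higher. Over Healthy, the proteasome median rose from -0.03 in DAT to 0.43 in Lepto and 0.54 in Outgroup, the order of these groups' shares of bright slides. Oxidative phosphorylation, heat shock, mature neutrophil, glucocorticoid and ribosomal medians rose in the same order, and the monocyte median did not. Whether slides account for these list differences between DAT and Lepto was not tested.

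Cathepsin E had the largest gap towards DAT, at 2300.2 ± 306 against 567 ± 111 in Lepto. Papilin (LOC490769), PAFAH2 (LOC478174), which inactivates platelet-activating factor, the lymphocyte factor Aiolos (LOC491020) and EFEMP2 (LOC476020), an elastic fibre protein, were also among the 8 largest, with ratios from 1.78 to 1.41. Towards Lepto, the largest gaps after HNRPK, an RNA-binding protein at -2.64, and FGL2 included the mannose-6-phosphate receptor (LOC477700), acid ceramidase (LOC482897), CMTM6 (LOC485622), TSG-6 (LOC476147), an inflammation-induced hyaluronan binder, and NT5C2 (LOC477809), with ratios from -2.39 to -2.08. TSG-6 stood at 934 ± 137 in DAT and 4001 ± 750.2 in Lepto. Of the 27 genes taken for this comparison, 7 had averages in the order of the shares of bright slides, among them TSG-6, PSMB1, LOC480290, GRP78, ATP5B, LOC477700 and LOC477809. In all, 683 averages were clearly higher and 1182 clearly lower in DAT, or 963 and 904 without centring.

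**Figure D3:**
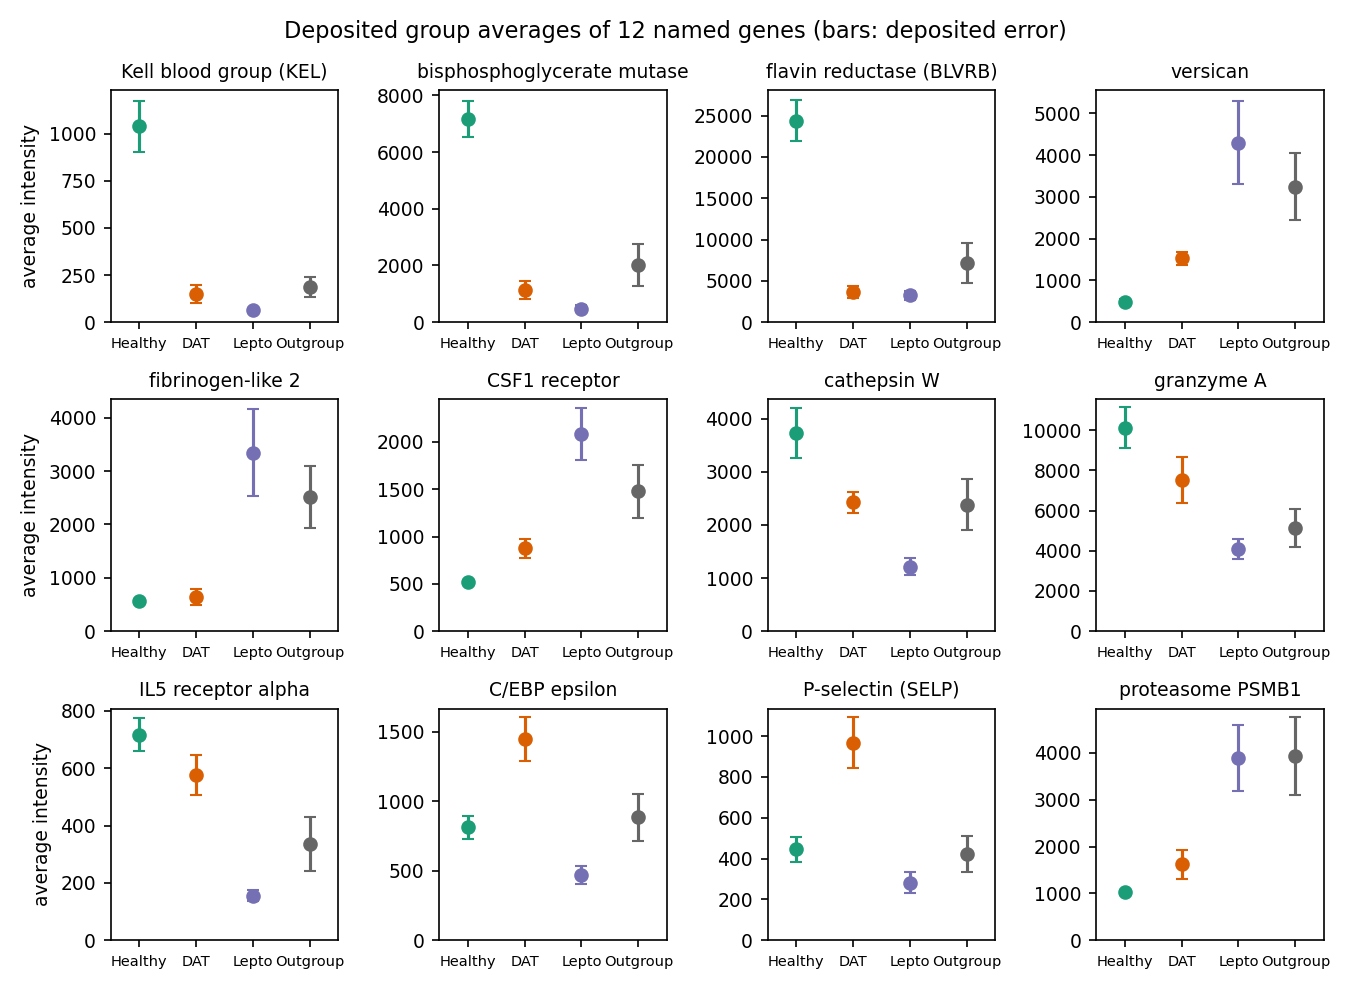
Deposited average intensity of 12 genes in the 4 groups on linear axes, with bars for the deposited error. KEL, BPGM and BLVRB were highest in Healthy, FGL2, versican and CSF1R were highest in Lepto, and P-selectin and C/EBP epsilon were highest in DAT.

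Over animals, limma called 6776 probes between DAT and Lepto, of which 3499 rose and 3277 fell in DAT. With slide as a fixed block, 158 rose and 240 fell, with a median size of 0.90 on the log2 scale. The dim slides alone gave 201 calls and the bright slides alone gave 0, with 1557 probes at an unadjusted p under 0.05. Within slides 3, 7, 9 and 12, which held at least 2 animals of each group, 0, 0, 0 and 1 probes were called by limma, 1665, 467, 1314 and 1789 had an unadjusted p under 0.05, and their differences correlated with those over all animals at r from 0.289 to 0.495. Values as deposited put 3.98% of the calls on the higher side in DAT against 51.6% after normalisation. With sex and age class as covariates 496 probes were called, and with slide added to these terms, 9.

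A nearest-centroid classifier on 50 probes assigned 39 of 51 animals to the right group when each animal was left out in turn, 24 of 30 DAT and 15 of 21 Lepto. The balanced accuracy was 75.7%, and the 95% exact binomial interval of the share correct was 62.5% to 87.2%. Permuted labels gave at most 72.6% in 100 permutations, for a permutation p of 0.0099, the smallest they can give. These permutations ignored slide. Leaving out each whole slide in turn gave 75.7% as well, where labels permuted within slides gave a median of 65.2% and at most 74.0% (p = 0.0099 again). With slide means taken away the balanced accuracy was 74.2%, over the 37 animals (22 DAT and 15 Lepto) on slides that held both groups. On the bright slides alone it was 70.8%, with 3 of 6 DAT animals right. Calling every array on a dim slide DAT gave 68.6% with no use of gene signals. Among males alone the classifier reached 74.1%, with 9 of 13 DAT and 15 of 19 Lepto animals right. DAT held 17 adults and Lepto 2. No run held age class constant, so the part that age plays in these accuracies is open.

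Outgroup averages correlated across genes on the log2 scale with those of Lepto at r = 0.989, of DAT at r = 0.956 and of Healthy at r = 0.927. These values lay in the order of the groups' shares of arrays on bright slides, 58.3%, 24.2% and 0%. Genes are not independent replicates. Against Healthy, the largest gaps were again Idax (LOC487887), LOC485023, CBL (LOC489369), Brain protein 44 (LOC480086) and EEF1A1 (LOC480975), with log2 ratios from 8.57 to 4.19. On the lower side were NHLRC1, the atypical cadherin CELSR1 (LOC481203), the protein kinase A subunit PRKAR2B (LOC475887) and LOC481213, from -3.52 to -3.19. Of 18 erythroid genes, 8 were clearly lower, with a median of -0.34, KEL at -2.52 and BPGM at -1.86. Of 10 monocyte genes, 5 were clearly higher and 2 lower, with a median of 0.90, versican at 2.70 and FGL2 at 2.12. The mature neutrophil list had a median of 0.73, with the Fc receptor FCGR3A (LOC478984) and the integrin ITGAM (LOC489928) at 1.69 and 0.97. Of 22 cell cycle genes, 0 were clearly higher and 1 clearly lower although their median was 0.78.

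Lists of protein and energy metabolism had medians towards Outgroup. Of 47 oxidative phosphorylation genes, 17 were clearly higher and 2 lower, with the Rieske protein (LOC476503) and SDHC (LOC478983) at 3.26 and 1.95. Medians were 0.44 for that list, 0.54 for the proteasome (9 of 30 clearly higher and 2 lower), with PSMC2 (LOC475896) and PSMB1 at 2.03 and 1.90, and 0.55 for ribosomal proteins (10 of 50 clearly higher and 2 lower), with RPL6 (LOC480924) and RPS3A (LOC608454) at 2.36 and 1.61. The chaperones GRP78 (LOC480726) and calnexin (CANX) stood at 2.05 and 1.54, in a list with a median of 0.61. In all, 1667 averages were clearly higher and 1839 clearly lower, or 1850 and 1586 without centring. Of the 24 genes taken for this comparison, 9 lay in the order of the shares of bright slides. Limma called 2035 probes over animals, 1076 higher and 959 lower in Outgroup. With slide as a fixed block it called 1158, 410 higher and 748 lower, with 678 in both fits. No slide held animals of both groups, and 1159, 1345, 1070 and 912 probes were called without Healthy replicates 1, 2, 3 and 4. Values as deposited put 98.5% of the calls on the higher side in Outgroup against 52.9% after normalisation.

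DAT had higher averages than Outgroup for IRF7 (LOC483406), at 19655 ± 3519.6 against 5924 ± 1485. HERC1 (LOC487592), described as exchange factor p532, the kinase MST1 (LOC477240), papilin (LOC490769) and a chondroitin-building enzyme (LOC482831) followed, with ratios from 1.35 to 1.29. Lower in DAT were 14-3-3 epsilon (LOC480049), ribophorin II (LOC477223), the splicing helicase DDX48 (LOC475922), ZNF207 (LOC480611) and SSR1, a part of the endoplasmic reticulum's protein channel, from -2.36 to -2.11. The cell cycle list had a median of -1.08, below every matched random list, with the spindle gene ASPM as its 1 clear gap of 22, at -1.26. Of 47 oxidative phosphorylation genes, 7 were clearly lower and 1 higher, with LOC480277 and NDUFB4 (LOC478577) at -1.26 and -1.14, and of 30 proteasome genes 6 were clearly lower, with PSMB10 (LOC489749) and PSMA1 (LOC486985) at -1.27 and -1.09. Heat shock genes had a median of -0.64 with 0 clear gaps. Over Healthy, the medians of the cell cycle, oxidative phosphorylation, proteasome and heat shock lists rose from DAT to Lepto to Outgroup, the order of their shares of bright slides. In all, 939 averages were clearly higher and 892 lower in DAT, or 1481 and 529 without centring. Of the 15 genes taken here, 7 lay in the order of the shares of bright slides, IRF7, 14-3-3 epsilon, ribophorin II, DDX48 and ZNF207 among them. Limma called 6456 probes over animals, of which 3581 rose and 2875 fell in DAT. Given slide as a fixed block, limma called 0, with 624 at an unadjusted p under 0.05. Within slides 3 and 4 it called 0, with 116 and 391 at an unadjusted p under 0.05, and values as deposited put 0.747% of the calls on the higher side against 55.5% after normalisation.

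Few averages or probes passed between Lepto and Outgroup. Of 13432 averages, 8 were clearly higher and 16 clearly lower in Lepto, or 12 and 8 without centring, and 2 of the 9 genes taken lay in the order of the shares of bright slides. Argininosuccinate synthetase (LOC480693), an enzyme of the urea cycle and arginine supply, stood at 321 ± 35.8 in Lepto and 175 ± 23.0 in Outgroup. Kidney-specific cadherin (LOC489770) and the fatty acid enzyme ACSL4 (LOC481018) had ratios of 0.73 and 0.71. Histone H3g (LOC488271), GATS (LOC489792), sorting nexin 19 (LOC479391), the kinase TESK1 (LOC474758) and TRIM28 were lower in Lepto, from -1.30 to -0.87. The cytotoxic list had a median of -0.45, with cystatin F (LOC485563) as its 1 clear gap at -0.68, and eosinophil and platelet lists had medians of -0.48 and -0.43 with 0 clear gaps. The cell cycle list had a median of -0.61 and the 12 MHC class II genes one of 0.25, also with 0 clear gaps. Limma called 18 probes over animals, 1 higher and 17 lower in Lepto, and 17 with slide as a fixed block, of which 7 were called in both fits. Within slides 2 and 3 it called 1 and 0, with 790 and 1925 at an unadjusted p under 0.05, and with each array centred on its median it called 1 higher and 3 lower.

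**Figure D4:**
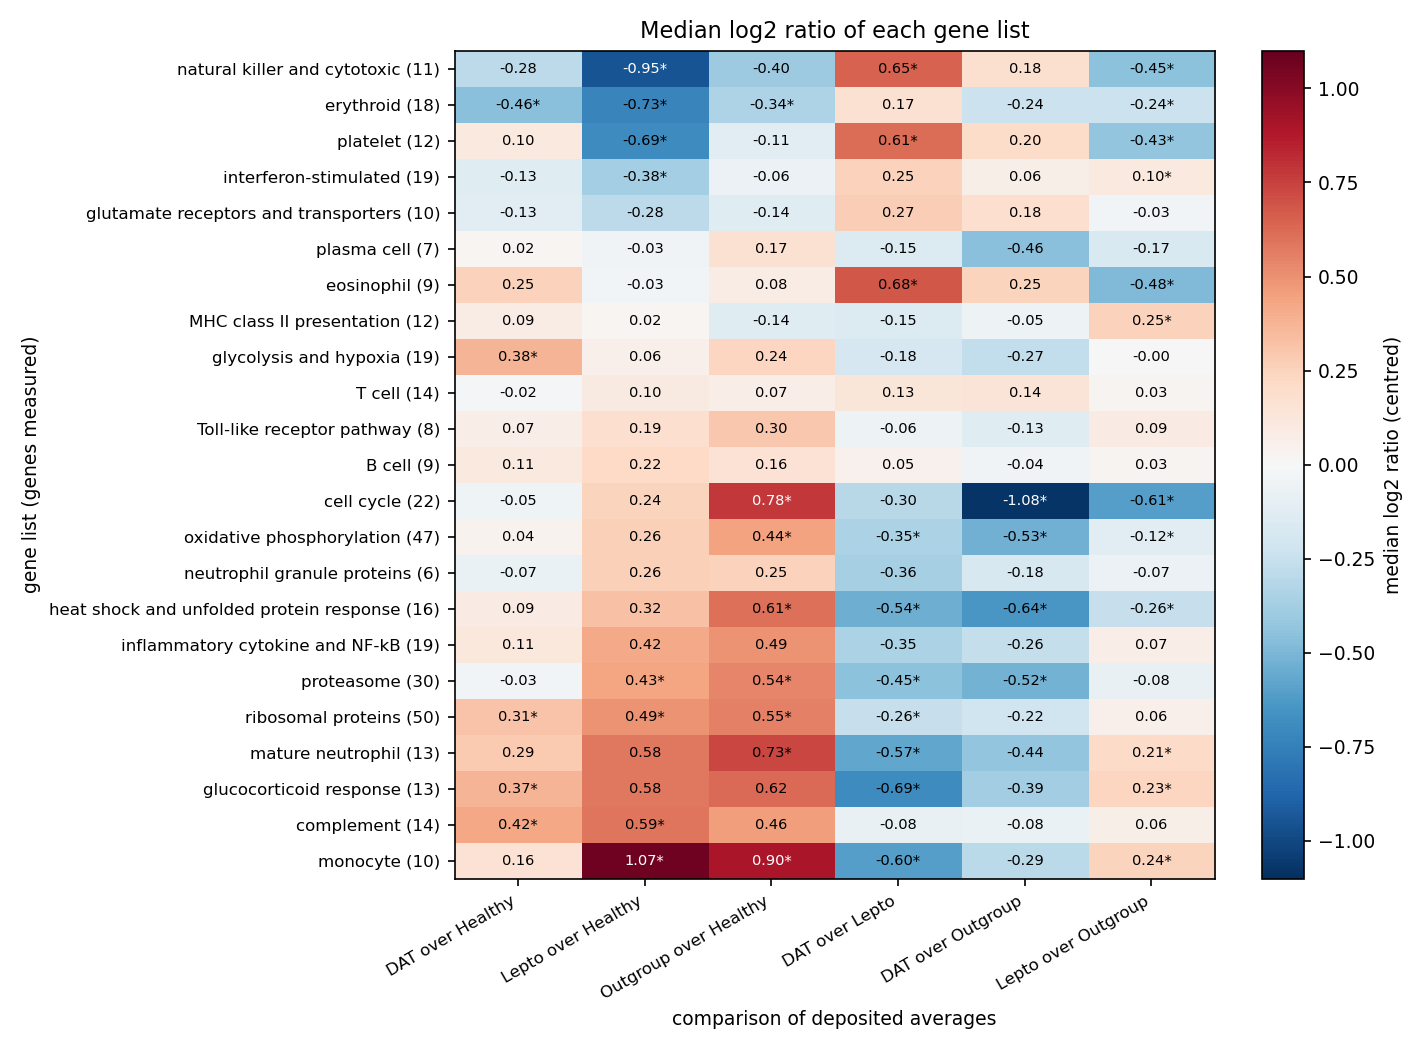
Median centred log2 ratio of deposited averages for 23 gene lists in 6 comparisons, red for higher and blue for lower in the group named first, with the number of genes measured in brackets. A star marks a median outside the 2.5 to 97.5 percentiles of 10000 matched random lists, such as the erythroid list in DAT over Healthy at -0.46.

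Within DAT, 6 animals had been labelled acute and 11 chronic, and no gene names belong to this comparison because the averages do not split the group. Limma called 0 probes between them, with 540 at an unadjusted p under 0.05, and 0 with slide as a random block, with 150. A fit with slide as a fixed block was not run for this comparison. All 6 acute animals were adult females, and among adult females, 6 acute against 4 chronic, 0 probes were called and 2056 had an unadjusted p under 0.05. In data simulated for this comparison, 2.0% of 200 probes changed by 1 on the log2 scale were recovered among 15743, and 66.0% of those changed by 2.

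Between females and males, with diagnosis and age class as covariates, limma called 8 probes, 1 higher and 7 lower in females. In the fit with slide as a fixed block it called 0 higher and 5 lower, and in values as deposited 0 higher and 2 lower. The difference between DAT and Lepto did not depend on sex at any probe past an adjusted p of 0.05 in limma, with 307 probes at an unadjusted p under 0.05 (349 with slide as a block), and Lepto held only 2 females.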

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

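All tests of explanations in this part were written after the results were seen. Among the 4 Healthy and the 6 acute DAT animals, array medians and 3 principal components showed no animal far from the others by Dixon's test, and no probe's difference between DAT and Lepto depended on sex past the threshold.

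Most of the 6776 calls between DAT and Lepto ended with slide in the model. Across the 6445 probes whose call ended with slide in the model, the difference ran against the bright minus dim difference among Outgroup arrays, with r = -0.913. Outgroup arrays belong to neither group. The median size of the DAT minus Lepto difference went from 0.79 to 0.22 on the log2 scale. These probes were picked by the loss of their call, so both values are partly set by that choice. Over all 15743 probes, without this choice, r was -0.829. The larger share of DAT arrays on dim slides may therefore account for many of these calls. Of the 201 probes called on the dim slides alone, 92.5% had the same sign on the bright slides. Differences between slides stay open for these calls, because that fit had no slide term. Slide 8 held 7 DAT arrays and 0 Lepto arrays, and slide 11 held 7 and 1. The share with the same sign over all probes was not computed, and differences of the slide sets correlated over all probes at r = 0.416. With sex, age class and slide as terms limma called 9 probes, with 1558 at an unadjusted p under 0.05. Since Lepto held 2 females and 2 adults, disease and the make-up of the groups cannot be told apart for the 201 probes. Of 100 splits of the animals, 1, the real one, gave as many as 6776, the highest other giving 3339. These splits ignored slide, so chance is not excluded where groups follow slides. Chance is excluded for the 398 calls with slide in the model: 1 of 100 exchanges within slides gave as many, the highest other giving 0.

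Of the 1245 calls between DAT and Healthy, 579 ended with slide in the model, where their median size went from 1.33 (median standard error 0.37) to 0.76 (0.40) on the log2 scale, and a shift of slide 5 stays open for them. Slide in the model takes such a shift away, so it is not the whole cause, since 666 of the calls (53.5%) were made again, with a median size of 2.04 (median standard error 0.49). Place on the slide cannot be told apart from diagnosis there, because Healthy and DAT arrays lay on opposite sides of slide 5 and 0 sides held both. With the side as a further term 1150 calls were made, and 549 of the 1245 probes (44.1%) were called again. Sex and age as additive terms are not the whole cause, since 81.9% of the 1245 probes were called again with them, with a median size of 1.77 (median standard error 0.45), and 62.7% with slide added. By calls, chance is excluded within slides (1 of 35 exchanges reached 1353, highest other 99). Over all animals, 1 of 100 splits reached 1245 (highest other 65). The 2925 probes at an unadjusted p under 0.05 were reached by 4 of 100 (highest other 5943). Splits over all animals ignored slide, so they do not exclude chance where groups follow slides. Stranding and the handling of controls were not tested.

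Lower erythroid averages in DAT cannot be told apart from the mix of bright and dim slides. If slide brightness were the cause, DAT averages would lie 36.4% of the way from Healthy to Outgroup. Over all 18 genes, each group divided by its median, the median log2 ratio was -0.39 where -0.15 was implied, with 14 genes below and 4 above that point, 5 and 1 of them by over 3 combined errors, too few to exclude brightness. An effect of slide 5 on these genes cannot be told apart from health either, because the deposited averages give 0 values for other animals of that slide alone. Diagnosis, sex and age also stay open for these genes, untested.

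Splits of all animals exchange animals across slides, while the consensus correlation of arrays within slides was 0.537. They therefore cover only a random draw of animals across slides, and chance where groups follow slides stays open. By calls, only the real split reached the 2915 of Lepto minus Healthy (1 of 100, highest other 3) and the 6456 of DAT minus Outgroup (1 of 100, highest other 39). By probes at an unadjusted p under 0.05, 4 of 100 reached the 5367 of Lepto minus Healthy (highest other 5953), which alone would leave chance open, and 1 of 100 the 8226 of DAT minus Outgroup (highest other 5320). With slide in the model DAT minus Outgroup had 0 limma calls, and 83 of 100 exchanges within slides gave as many as its 624 probes at an unadjusted p under 0.05 (highest other 5478), so chance is not excluded there. Chance also stays open where the 95% upper bound of the share passed 5%: 2 of 100 splits reached 2035 for Outgroup minus Healthy (highest other 3000), 4 of 100 reached 18 for Lepto minus Outgroup (highest other 5373), 4 of 100 exchanges reached its 17 with slide in the model (highest other 122), and 3 of 100 reached 8 for females minus males (highest other 3369). For Lepto minus Healthy with slide in the model only 5 exchanges exist, of which 1, the real one, reached 2411, too few to tell. For acute minus chronic, with 0 limma calls, 41 of 100 splits gave as many as its 540 probes at an unadjusted p under 0.05 (highest other 6494), so chance is not excluded either. Whether splits that called several times the real count followed the slide sets was not tested. In a separate comparison, not among the drawn splits, 9695 probes were called between DAT animals on bright and on dim slides.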

How the results depend on the processing

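Runs on bright or dim slides alone, with the slide set as a block, with the side of the slide as a term, labels permuted within slides, without Outgroup replicate 6 and DAT replicate 15, with each acute animal left out, the classifier runs by slide set, and the runs on averages without centring, with a floor or without dim averages were chosen after the data were seen. No paired analysis was possible because replicate numbers only count the animals of a group. Counts over all animals were 1245, 2915, 6776, 2035, 6456 and 18 for DAT minus Healthy, Lepto minus Healthy, DAT minus Lepto, Outgroup minus Healthy, DAT minus Outgroup and Lepto minus Outgroup. Of the other counts of probes, 64 lay within 1.5 times their count here and 74 did not, given next by setting, with the number at an unadjusted p under 0.05 beside each limma count of 0; except where the setting takes away probes or animals, tightens the threshold or adds a term, the cause was not tested. With slide as a fixed block the counts outside that range were 398 for DAT minus Lepto, 1158 for Outgroup minus Healthy, 0 (624 unadjusted) for DAT minus Outgroup and 5 for females minus males. With slide as a random block they were 823 for DAT minus Lepto, 1189 for Outgroup minus Healthy, 0 (1276 unadjusted) for DAT minus Outgroup and 76 for Lepto minus Outgroup. With slide and the side of the slide as fixed terms they were 1897 for Lepto minus Healthy, 313 for DAT minus Lepto, 1215 for Outgroup minus Healthy, 0 (507 unadjusted) for DAT minus Outgroup and 4 for Lepto minus Outgroup. With the slide set as a fixed block they were 2783 for DAT minus Healthy, 839 for DAT minus Lepto, 1255 for Outgroup minus Healthy and 0 (1659 unadjusted) for DAT minus Outgroup. On the dim slides alone they were 3719 for DAT minus Healthy, 201 for DAT minus Lepto, 822 for Outgroup minus Healthy, 1 for DAT minus Outgroup and 1 for Lepto minus Outgroup. On the bright slides alone they were 0 (1557 unadjusted) for DAT minus Lepto, 0 (380 unadjusted) for DAT minus Outgroup and 0 (1019 unadjusted) for Lepto minus Outgroup. With sex and age class they were 1538 for Lepto minus Healthy, 496 for DAT minus Lepto, 1005 for Outgroup minus Healthy, 3736 for DAT minus Outgroup and 0 (897 unadjusted) for Lepto minus Outgroup. With sex, age class and slide they were 3475 for DAT minus Healthy, 9 for DAT minus Lepto, 0 (816 unadjusted) for DAT minus Outgroup and 0 (784 unadjusted) for Lepto minus Outgroup. Among adult males the count was 7871 for DAT minus Healthy, between slides 11 and 5. On slide 5 alone it was 2921 for DAT minus Healthy. Array weights gave 6949 for DAT minus Healthy, 10696 for Lepto minus Healthy, 12338 for DAT minus Lepto, 9896 for Outgroup minus Healthy, 11527 for DAT minus Outgroup and 10 for Lepto minus Outgroup. Values as deposited gave 6605 for Lepto minus Healthy, 1782 for DAT minus Lepto, 10430 for Outgroup minus Healthy, 2 for Lepto minus Outgroup and 2 for females minus males. Keeping the 7872 brighter probes the counts were 366 for DAT minus Healthy, 1302 for Lepto minus Healthy, 3458 for DAT minus Lepto, 751 for Outgroup minus Healthy, 3262 for DAT minus Outgroup and 10 for Lepto minus Outgroup. At an adjusted p of 0.01 they were 773 for DAT minus Healthy, 1539 for Lepto minus Healthy, 2105 for DAT minus Lepto, 834 for Outgroup minus Healthy, 655 for DAT minus Outgroup and 2 for Lepto minus Outgroup. Fits on only the groups compared gave 977 for Outgroup minus Healthy and 2 for Lepto minus Outgroup. For Lepto minus Outgroup, 2 probes were called on the first array of each animal, 4 with each array centred on its median, 8 with a pseudocount, 3 without Lepto animals with a second disease and 6 without Outgroup replicate 6 and DAT replicate 15. Leaving out each Healthy animal gave 710 to 1015 probes for DAT minus Healthy, 1642 to 2152 for Lepto minus Healthy and 912 to 1345 for Outgroup minus Healthy, and leaving out each acute animal gave 0 in all 6 runs (at most 1328 unadjusted). Without the dimmer averages, clear gaps numbered 1113 for DAT over Healthy, 2175 for Lepto over Healthy, 799 for DAT over Lepto, 1782 for Outgroup over Healthy, 639 for DAT over Outgroup and 10 for Lepto over Outgroup. The share of animals that the classifier assigned correctly stayed within its interval in all 7 other runs, and balanced accuracy ran from 68.3% on 10 probes to 81.4% on 200. The medians of gene lists that stood apart kept their sign without centring and with the mean of all averages of a symbol, where 87 of these medians moved by less than the standard error of their members' ratios and 7 by more. Named ratios kept their sign without centring, where 129 moved by less than their deposited error and 2 by more. Slide, sex and age alternatives for gene lists and named genes, estimated correlations, and deposited averages in place of means over animals were not run, since probes could not be named. Signal over background limits dim probes, and background was not used here.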

Other observations

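No tests in this part were planned before the data were seen. The genes given here were picked after their averages were seen. DLA-DRB1, an MHC class II chain, had averages of 144861 ± 10593 in Healthy, 38483 ± 4254 in DAT, 22451 ± 5699.5 in Lepto and 37928 ± 11472 in Outgroup, with clear gaps of all 3 groups to Healthy. None of the genes that follow had a clear gap in any of the 6 comparisons. DLA-DRA1, the partner chain of DLA-DRB1, stood at 23772 ± 1842, 32182 ± 2619, 51016 ± 10180.0 and 37706 ± 6679 in the same order. The interleukin-1 decoy receptor IL1R2 (LOC481330) stood at 1356 ± 100.4 in Healthy, 3522 ± 753 in DAT, 29785 ± 11112 in Lepto and 19375 ± 6866 in Outgroup. PCNA (LOC477166), the clamp of DNA replication, stood at 723 ± 108, 646 ± 142, 1314 ± 282 and 2795 ± 817 in the same order, and RRM2 (LOC482963), which makes DNA precursors, at 790.2 ± 192, 771 ± 204, 1126 ± 171 and 2194 ± 729.

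Repeat arrays of the same animal correlated across probes at r = 0.988 on the same slide and between 0.764 and 0.971 on different slides of the same brightness (6 pairs from 4 animals). The lowest values, 0.764 and 0.808, came from Lepto replicate 4 and its array on slide 4. Outgroup replicate 6 and DAT replicate 15 had the highest array medians, 3249 and 3277. Lepto animals on bright slides differed from Lepto animals on dim slides at 11208 probes in limma.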
